A study of Mus musculus with 54 samples.

How the data were processed

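Late proximal tubules of mouse kidney, negative for SGLT2 and positive for the lectin LTL, were isolated by laser capture, 70 to 80 per sample. Per the labels, RNA was extracted with a PicoPure kit and libraries were prepared from 0.5 ng of total RNA (DV200 above 30%) with a SMARTer stranded total RNA kit. The expression table holds log10 values of TPM, which the authors computed on the mouse build GRCm38 before it was deposited. The aligner, the annotation, any scaling between libraries and the number of reads are not given in the sources used here, so counting noise cannot be told from other spread. The table's title says that outliers were left out. It has 52 columns for the 54 samples of the labels. The samples without a column are Akita wild-type dapagliflozin replicate 2 and Akita wild-type semaglutide replicate 1.

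Values were turned back to TPM, and blank cells were taken as 0. Of the 52 libraries, 51 summed to more than the nominal total of TPM. Of 19068 genes, 15424 with a mean of at least 1 TPM were tested. Of the gene identifiers, 19033 matched a symbol, and positions came from GENCODE vM21. Replicates were numbered here in the order of the labels, which give each library a number of its own. Mitochondrial ribosomal RNA made up 20.3 to 52.3% of a library. The first principal component held 8.59% of the variance and correlated with the score of other cell types at -0.807. Library pairs correlated at 0.847 to 0.955 (median 0.926 within and 0.923 between groups).

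Log2(TPM + 1) was fitted with 9 group means in limma 3.58.1 under R 4.3.3 (eBayes with trend and robust settings; files were read with the package data.table, version 1.17.8), with 18 comparisons. Genes passed at an adjusted p under 0.05 (Benjamini-Hochberg over all tested genes). Counts at an unadjusted p under 0.05 are given for scale alone, since a share near 0.05 of genes falls there with no effect. In comparisons where limma called 0 genes these counts made up 2.39 to 5.77% of the tested genes. Gene lists written before the data were examined, 49 of 50 with at least 4 tested members, were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation. List scores of 2 groups were compared with exact permutation tests. TPM are given as mean ± SD and log2 changes with their SE.

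Genes were named by rule. In the main comparisons these are up to 8 higher and 8 lower genes with the smallest adjusted p under 0.05 and a log2 change of at least 0.5 in size, without predicted genes, and up to 3 members of each list that passed camera. In the other comparisons up to 3 genes each way are named. Slc5a1 and Slc5a2 are given in every group. Where fewer than 4 genes passed in a main comparison, the 2 with the smallest p each way are given as values. Some genes that the rule gives are not reported here.

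The test was run on simulated data made by reshuffling libraries and changing 200 of the 15424 genes in each of 10 rounds. Changes of log2 0.5, 1 and 2 were recovered in 8.35, 53.2 and 89.2% of genes for diabetes in vehicle samples, with 4.91% false calls. The shares were 6.85, 51.7 and 92.6% for semaglutide (1.37% false), 50.5, 93.2 and 98.9% for averaged diabetes (1.69% false), 56.1, 93.9 and 99.3% for averaged knockout (18% false), and 53, 92 and 99.1% for averaged dapagliflozin (4.82% false). In the unchanged data, preset camera called 5.3 to 11 of 49 lists per round and camera with an estimated correlation 0. Libraries were dealt at random over all groups in these rounds, so a larger spread within a single group is not in the shares. For diabetes in vehicle samples, other splits of the real libraries called up to 408 genes. The 4.91% may therefore understate false calls in that comparison.

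Alternatives chosen before the data were examined were a pseudocount of 0.1, no filter, rescaling by the median ratio, array weights, a fit of the compared groups alone, the library number or a score of other cell types as a covariate, each library left out, an estimated correlation between genes, and shared vehicle libraries in the relation between changes. Chosen afterwards were the score of the S1 and S2 segments as a covariate, leaving out the 3 libraries lowest on the first component, and lists without Slc5a1. For the gene lists, the score of other cell types, the sum of TPM and the percent of mitochondrial rRNA as covariates and leaving out single libraries were also chosen then, as was leaving out single libraries for the relation between changes. These 3 libraries, nondiabetic wild-type vehicle replicates 1 and 2 and nondiabetic knockout dapagliflozin replicate 3, had scores of other cell types of 0.712, 0.942 and 0.597. Raw reads were not analysed here.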

Results

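The data describe RNA from the late proximal tubule, the S3 segment, of the mouse kidney. Tubules that stained with the lectin LTL, which binds proximal tubule, and lacked SGLT2, the glucose carrier of the early proximal tubule, were cut out by laser, 70 to 80 per sample, and total RNA was sequenced. The animals were male DBA mice of 14 weeks, either nondiabetic or diabetic through the Akita mutation of the insulin gene Ins2, a model of type 1 diabetes. Both kinds were wild type or knockout for Sglt1 (Slc5a1), the glucose carrier of the late proximal tubule, and received vehicle or dapagliflozin, an SGLT2 inhibitor given at 10 mg per kg of diet, for 2 weeks. A further group of wild-type Akita mice received semaglutide, a GLP-1 receptor agonist, at 3 nmol per kg per day. The labels give 54 samples in 9 groups. Expression values cover 52 of them, with 5 libraries each in the dapagliflozin and semaglutide groups of wild-type Akita mice and 6 in each other group. Values are in TPM, a measure scaled to gene length and to the library, and the number of reads per library is unknown. Between 16206 and 18421 genes had a value in a library, and 15424 genes with a mean of at least 1 TPM were tested. The tests measure the spread between samples, since the labels do not say that each sample came from a different animal.

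Slc5a1 (ENSMUSG00000011034, chromosome 5, 33104219 to 33162870, GRCm38) was near 0 in every knockout group and present in every wild-type group. Its mean was 55 ± 18.6 TPM (SD, n = 6) in nondiabetic wild-type vehicle samples and 86.2 ± 13.5 TPM (SD, n = 6) in Akita wild-type vehicle samples. It was 64.6 ± 17.9 TPM (SD, n = 6) with dapagliflozin in nondiabetic wild-type samples, 73.3 ± 18.1 TPM (SD, n = 5) with dapagliflozin in Akita wild-type samples, and 63.4 ± 4.25 TPM (SD, n = 5) with semaglutide. The means of the 4 knockout groups lay between 0.776 and 0.828 TPM, and no knockout library exceeded 1.34 TPM. The diabetes difference of Slc5a1 in vehicle samples, log2 0.71 (SE 0.20), had an adjusted p of 0.104 in limma and did not pass over all genes.

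Slc5a2, which encodes SGLT2 and marks the S1 and S2 segments that the dissection was meant to leave out, ranged from 3.93 to 205 TPM between libraries, a 52.2-fold range. Its group means lay between 27 and 67.1 TPM, and in most groups the SD was as large as the mean. A difference of Slc5a2 with diabetes was not detected in vehicle wild-type samples (log2 -0.36, SE 0.86).

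**Figure D1:**
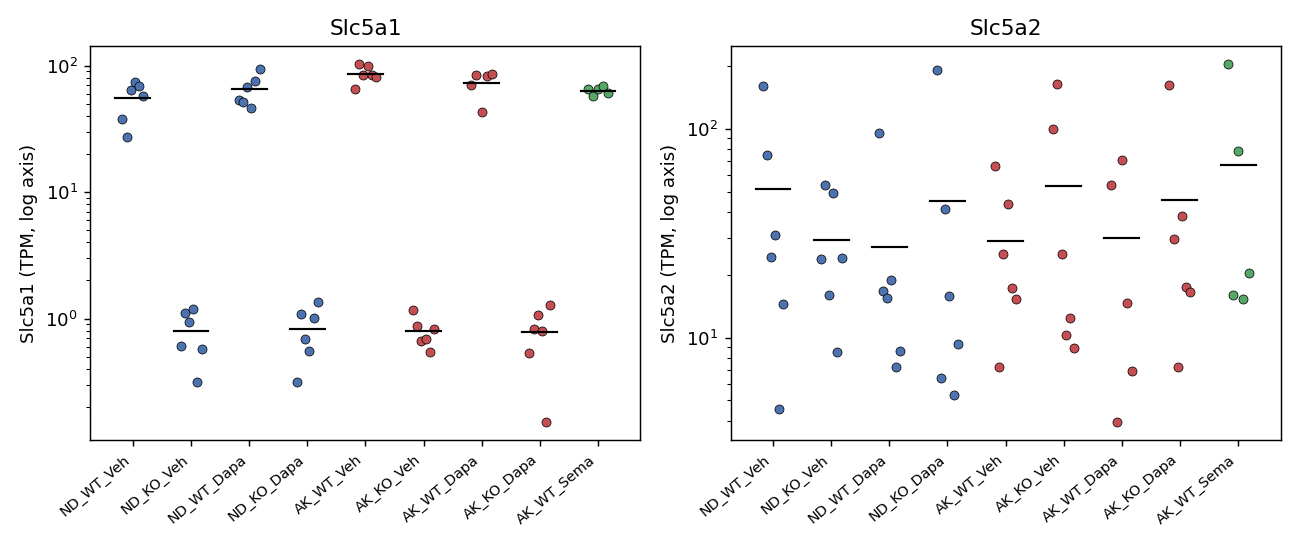
Slc5a1 and Slc5a2 in TPM (log axis) in each of the 52 libraries, by group; each point is a library and each line the group mean. Slc5a1 stays at or below 1.34 TPM in the knockout libraries, and Slc5a2 spans 3.93 to 205 TPM across libraries.

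Diabetes in wild-type mice on vehicle raised 52 genes and lowered 8 in S3 tubules (6 Akita against 6 nondiabetic libraries). Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase, rose 3.31-fold, from 39.8 ± 11.6 to 131 ± 27.9 TPM (SD, n = 6 each). Ctnna2, a catenin that links cadherins to actin (ENSMUSG00000063063, chromosome 6), rose 4.2-fold, from 4.58 ± 1.73 to 21.8 ± 6 TPM. Afm, the vitamin E-binding protein afamin, rose 2.55-fold to 58.4 ± 12.6 TPM. Ccng1, the p53-induced cyclin G1, rose 2.77-fold to 91 ± 15.1 TPM.

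Further genes that rose were Gc, the vitamin D-binding protein (log2 3.22, SE 0.56), Fam171b (log2 1.74, SE 0.27) and Ugt1a10, a glucuronosyltransferase (log2 3.49, SE 0.53). Ugt1a10 shares its last exons with the other genes of its cluster, so its reads are uncertain. For each of these 7 genes all 6 Akita libraries lay above the nondiabetic median, and the limma adjusted p lay between 5.19e-06 and 0.000691. Among the 8 lower genes were Gpc1, a cell-surface heparan sulfate proteoglycan (log2 -1.35, adjusted p 0.00474, and 0.15 in a fit of the compared groups alone), and Vwf, the endothelial von Willebrand factor (log2 -1.53, adjusted p 0.00844). The rest were Id1, Sema3g, the xanthine oxidoreductase gene Xdh, the interferon-inducible Gbp4, the leukocyte phosphatase Ptpn22 and Bcas3, with log2 changes from -1.69 for Id1 to -0.61 for Bcas3.

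Targets of the transcription factor p53 rose as a group in diabetic vehicle samples. Of 13 tested members of this list, 5 rose over all genes and 10 when adjusted over the list alone, with a mean log2 change of 0.78 over the list (camera with an estimated correlation, adjusted p = 0.000112). Mdm2, the ubiquitin ligase of p53, rose from 47.7 ± 4.07 to 87.5 ± 12.2 TPM (SD, n = 6 each), and Phlda3 from 1.94 ± 1.14 to 8.94 ± 2.52 TPM. The other members past the threshold, named after their values were seen, were Zmat3 (log2 0.67) and the cell cycle inhibitor Cdkn1a (log2 1.46). Bbc3, Perp and Sesn1, at log2 -0.29, -0.08 and 0.01, did not pass. As a score, the mean log2(TPM + 1) of the list, p53 targets stood at 2.91 ± 0.20 in nondiabetic and 3.69 ± 0.15 in Akita vehicle samples (SD, n = 6 each). All 6 Akita scores lay above all 6 nondiabetic ones (2-sided exact permutation p = 0.00216, the smallest this design allows, and 0.0707 after adjustment over 49 lists). The sum of TPM over all genes also differed, at 1420000 ± 323000 in nondiabetic and 1860000 ± 251000 in Akita vehicle libraries, and mitochondrial rRNA made up 33.4 ± 6.57% and 40.1 ± 5.91% of it (SD, n = 6 each).

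**Figure D2:**
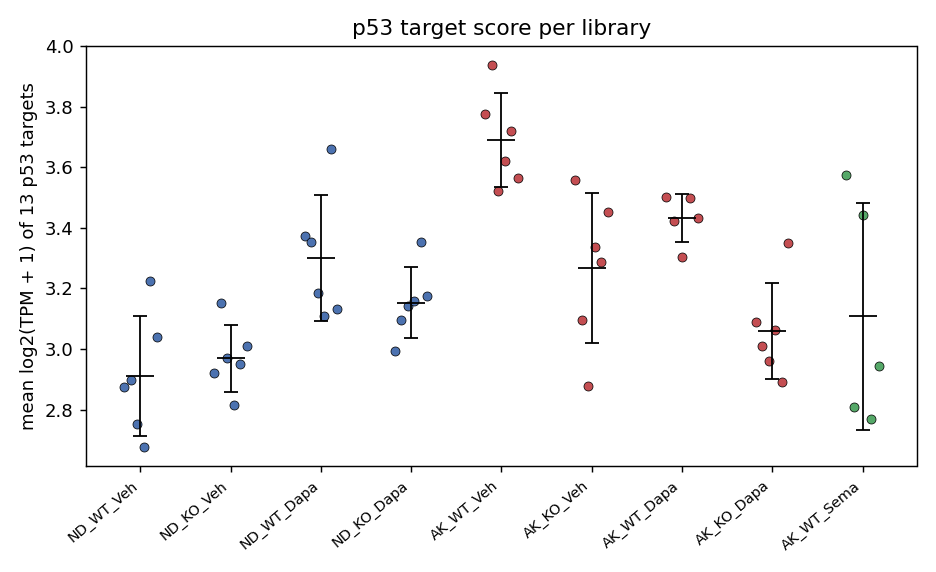
Score of 13 p53 targets, as mean log2(TPM + 1), in each library by group; points are libraries and bars give the mean ± SD. The score is 2.91 in nondiabetic and 3.69 in Akita wild-type vehicle samples, and 3.11 with semaglutide.

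Some genes of fructose and sugar handling were also higher in diabetic vehicle samples. As groups, polyol and fructose metabolism and glucose transporters passed camera with its preset correlation only (adjusted p = 0.0932 and 0.0688 with an estimated correlation). Of the 9 tested genes of polyol and fructose metabolism, 3 rose over all genes and 5 adjusted over the list alone. Tkfc, the triokinase (270 ± 80.2 to 465 ± 67.3 TPM), and Slc2a5, the fructose carrier (228 ± 150 to 535 ± 107 TPM; SD, n = 6 each), were among those past the threshold over all genes. Of the 11 glucose transporters, Slc2a5 and Slc5a10, a mannose and fructose carrier, rose, the latter from 435 ± 190 to 1060 ± 171 TPM. Adjusted over the list alone, 6 glucose transporters rose and 1, Slc2a1 (log2 -0.47), fell. Pklr, the liver and kidney pyruvate kinase, rose by log2 1.37 (SE 0.31), Ephx1, the microsomal epoxide hydrolase, by log2 1.73 (SE 0.33) and the glutathione transferase Gsta3 by log2 1.19 (SE 0.28).

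Preset camera called 20 of 49 lists for diabetes in vehicle samples, and p53 targets were the list that also passed with an estimated correlation. Markers of some other cell types had lower means in the Akita libraries, none past the threshold with an estimated correlation. The mean log2 change was -0.27 for endothelium, -0.47 for macrophages and dendritic cells and -0.46 for stroma, pericytes and smooth muscle (adjusted p = 0.288, 0.123 and 0.315 with an estimated correlation). Without the 3 libraries with the most RNA of other cells, 53 genes passed, 36 of them among the 60. The count was 148 without nondiabetic vehicle replicate 5 and 39 without Akita vehicle replicate 4. Of the 25 genes past the threshold that the naming rule gave, 13 kept their call whichever library was left out. The other 12 lost it at least once, and the highest adjusted p was, among others, 0.0549 for Vwf, 0.132 for Tkfc and Pklr and 0.179 for Slc2a5 (each without nondiabetic vehicle replicate 2 in this comparison), 0.12 for Id1 and 0.138 for Ptpn22 (each without Akita vehicle replicate 1), 0.138 for Xdh, 0.122 for Gsta3 and 0.148 for Bcas3 (each without Akita vehicle replicate 5), 0.142 for Sema3g (without nondiabetic vehicle replicate 1) and 0.126 for Gbp4 (without nondiabetic vehicle replicate 6).

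Averaged over genotype and over vehicle and dapagliflozin, diabetes raised 121 genes and lowered 28 (23 Akita against 24 nondiabetic libraries). Afm rose 1.78-fold, from 26.2 ± 9 to 46.6 ± 12.2 TPM (SD, n = 24 and 23), Pklr 2.14-fold, from 49.3 ± 25.1 to 99.7 ± 29.9 TPM, and Gpd2 1.78-fold, from 65.6 ± 29.7 to 110 ± 25.5 TPM. Ctnna2, Fam171b, Ugt1a10 and Tbc1d31 rose as well, as did Folh1, a folate and glutamate carboxypeptidase (log2 0.90, SE 0.14). Slc9a8, a sodium-proton exchanger, fell from 224 ± 71.6 to 133 ± 37.9 TPM, and Laptm5, a lysosomal protein of leukocytes, from 6.39 ± 2.69 to 3.25 ± 1.74 TPM. Gpc1, Rhpn2, the long noncoding RNA Neat1, the matrix protein gene Tnc, Arhgap25 and the calcium channel gene Ryr2 fell by log2 0.53 to 0.79.

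Sugar-metabolising genes were among those that rose in the averaged comparison. Of 9 genes of polyol and fructose metabolism, 5 rose over all genes and 8 adjusted over the list alone, with all 9 above 0 and a mean log2 change of 0.42 (adjusted p = 0.045 with an estimated correlation). Tkfc (log2 0.49), Slc2a5 (log2 0.89), Khk, the fructokinase (log2 0.49), and Sord, sorbitol dehydrogenase (log2 0.36), were among them. Targets of the glucose-sensing factors ChREBP and MondoA rose as a group (adjusted p = 0.0242 with an estimated correlation), 4 of 10 over all genes and 6 adjusted over the list alone, led by Pklr, while 1, Mlxip, fell over the list alone. Glucose transporters rose as a group (adjusted p = 0.045 with an estimated correlation), with 3 of 11 past the threshold over all genes: Slc5a10 (log2 0.75), Slc2a5 and Slc2a2, the basolateral glucose carrier (log2 0.67). Adjusted over the list alone, 5 rose and 1 fell.

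P53 targets rose in the averaged comparison too (3 of 13 over all genes, 6 adjusted over the list alone, mean log2 0.28, adjusted p = 0.0242 with an estimated correlation), with Ccng1 at log2 0.62, Mdm2 at 0.36 and Zmat3 at 0.33. The score differed between Akita and nondiabetic samples by 0.78 and 0.30 in wild-type and knockout vehicle samples, and by 0.13 and -0.09 with dapagliflozin (2-sided exact permutation p = 0.00216, 0.026, 0.203 and 0.279). Targets of the antioxidant factor NRF2 rose as a group (2 of 21 over all genes, 8 adjusted over the list alone, adjusted p = 0.045 with an estimated correlation). Its members past the threshold were Ephx1 (log2 0.72) and the transketolase gene Tkt (log2 0.37). Markers of macrophages and dendritic cells fell as a group (0 of 13 over all genes, 6 adjusted over the list alone, adjusted p = 0.045 with an estimated correlation), with C1qc at log2 -0.46 and H2-Aa at log2 -0.50. The list of failed-repair proximal tubule cells fell as a group with 0 of 13 members past either threshold (adjusted p = 0.045 with an estimated correlation). Its members with the smallest p were Vcam1, an adhesion molecule (log2 -0.41), Cd74, which also stands in the macrophage list (log2 -0.49), and the cytokine gene Il34 (log2 -0.53).

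Endothelial and interferon-response genes, at mean log2 -0.21 and -0.26, had an adjusted p of 0.0868 and 0.0808 with an estimated correlation. Without the 3 libraries with the most RNA of other cells 74 genes passed, 67 of them among the 149, and the estimated-correlation test then kept ChREBP and MondoA targets and p53 targets, with polyol and fructose metabolism at an adjusted p of 0.0536, glucose transporters at 0.0704, NRF2 targets at 0.087, failed-repair proximal tubule at 0.123 and macrophage and dendritic cell at 0.125. The count was 97 without nondiabetic wild-type vehicle replicate 2 and 97 without Akita wild-type dapagliflozin replicate 3. With single libraries left out, the highest adjusted p was 0.0552 for Ryr2 (without Akita wild-type dapagliflozin replicate 3) and 0.054 for Slc2a2 (without replicate 1 of that group). For the lists, with an estimated correlation, it was 0.0675 for polyol and fructose metabolism (without nondiabetic knockout vehicle replicate 3), 0.0675 for NRF2 targets and failed-repair proximal tubule, 0.079 for macrophages and dendritic cells (without nondiabetic wild-type dapagliflozin replicate 5) and 0.0844 for glucose transporters (without nondiabetic wild-type vehicle replicate 5). Of the 47 libraries left out in turn, 16 ended the call of polyol and fructose metabolism, 20 that of NRF2 targets, 19 that of failed-repair proximal tubule, 25 that of macrophages and dendritic cells and 24 that of glucose transporters, and 0 that of p53 targets or of ChREBP and MondoA targets. With the percent of mitochondrial rRNA as a covariate these 5 lists had an adjusted p of 0.0505 with an estimated correlation, and with the sum of TPM macrophages and dendritic cells had 0.0503. In each of 2 other fits, with the score of other cell types as a covariate or without the 3 libraries, Tnc, Arhgap25, Khk and Ryr2 did not pass (highest adjusted p 0.0754, 0.099, 0.0859 and 0.081), nor did Zmat3 without the 3 libraries (0.0678). Ryr2 was also lost with array weights and without any of 4 single libraries.

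**Figure D3:**
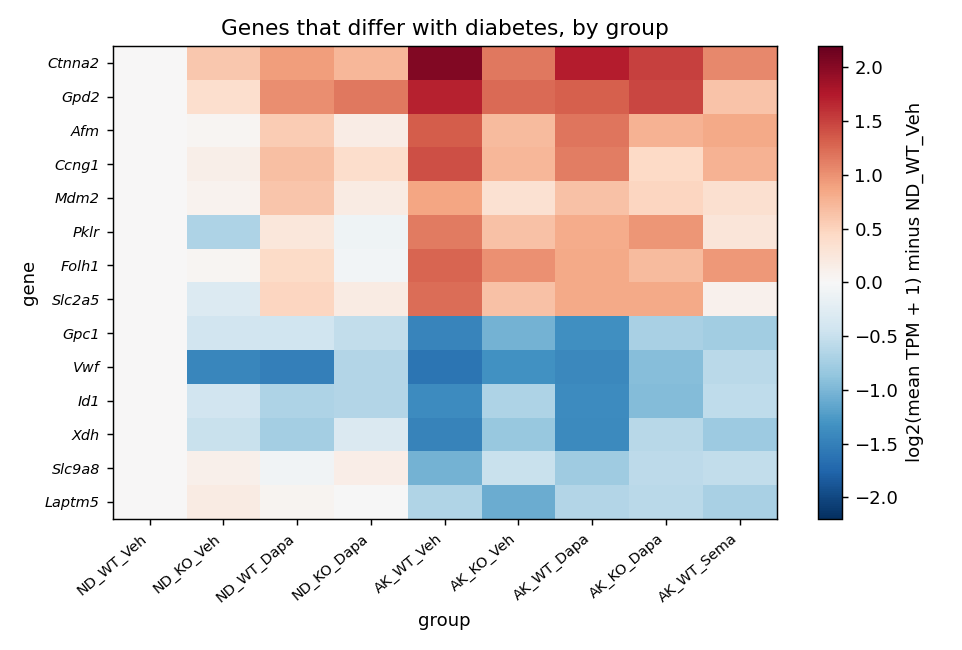
Log2(mean TPM + 1) of 14 genes in the 9 groups, minus that of nondiabetic wild-type vehicle samples, as colour. Gpd2, Ctnna2 and Afm are higher in Akita wild-type vehicle samples, with limma log2 changes of 1.73, 2.07 and 1.35, which are means of log2 values and differ slightly from the colours.

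The knockout of Sglt1, averaged over diabetes and drug (24 knockout against 23 wild-type libraries), changed 8 genes, of which 7 lie on chromosome 5. Slc5a1 fell from 69.7 ± 19.9 to 0.797 ± 0.319 TPM (SD, n = 23 and 24; log2 -5.26, SE 0.10, adjusted p 6.6e-40). Abhd1 (ENSMUSG00000006638, chromosome 5, 30950066 to 30955091), a gene of the hydrolase-fold family, rose 5.6-fold, from 6.36 ± 1.74 to 40.6 ± 12.8 TPM, and was higher in all 24 knockout libraries than the wild-type median. Tyms, thymidylate synthase (chromosome 5, 30058202 to 30073617), fell from 8.69 ± 3.83 to 2.9 ± 1.88 TPM, and Cgref1 (chromosome 5, 30933143 to 30945591) from 196 ± 48.7 to 123 ± 32.6 TPM. Sema3c, a secreted guidance factor (chromosome 5, 17574281 to 17730268), fell from 42.1 ± 13.8 to 23.6 ± 13.9 TPM.

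The other 3 genes, predicted ones named after their values were seen, were Gm43694 (log2 -2.34), Gm15936, a pseudogene that lies inside Slc5a1 (log2 -1.54), and Gm9973 on chromosome 13 (log2 1.30). In vehicle samples alone, 3 genes passed in nondiabetic mice and 4 in Akita mice, Slc5a1, Abhd1 and Gm43694 among both. In Akita mice Ugt1a10 also fell, from 16.9 ± 15.7 to 1.13 ± 0.402 TPM (SD, n = 6 each; adjusted p 0.0205, and 0.187 without Akita wild-type vehicle replicate 1), and 7 genes passed without Akita wild-type vehicle replicate 2. The Ugt1a10 call was lost with a pseudocount of 0.1 and on leaving out any of 5 single libraries. The interaction of diabetes and knockout called 0 genes in limma, with 618 at an unadjusted p under 0.05.

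**Figure D4:**
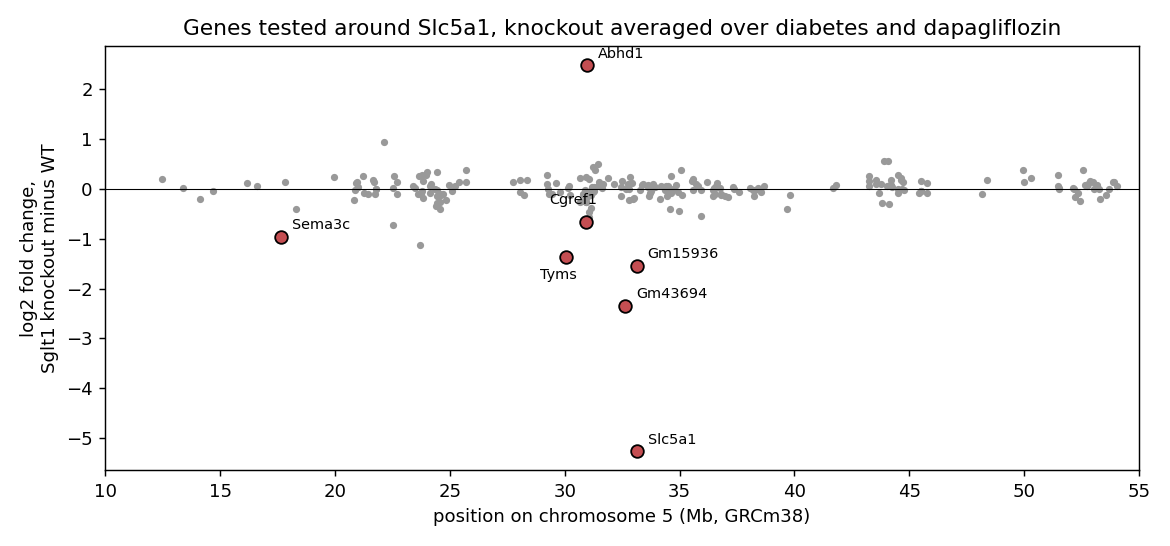
Log2 change in Sglt1 knockout, averaged over diabetes and drug, against position on chromosome 5 (10 to 55 Mb, GRCm38); each point is a tested gene and red points passed the limma threshold. Slc5a1 lies at 33104219 and falls by 5.26 on the log2 scale, and Abhd1, 2.15 Mb away, rises by 2.48.

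P53 targets fell in knockout samples averaged over diabetes and drug (0 of 13 over all genes, 5 adjusted over the list alone, mean log2 -0.22, adjusted p = 0.0182 with an estimated correlation), among them Phlda3 at log2 -0.78, Ccng1 at -0.35 and Mdm2 at -0.26. Interferon-response genes rose as a group (0 of 22 over all genes, 4 adjusted over the list alone, adjusted p = 0.0497 with an estimated correlation), with Iigp1 at log2 0.75. In nondiabetic vehicle samples p53 targets were at mean log2 0.06 with the knockout (adjusted p = 0.977 with an estimated correlation). The fall of the glucose transporters came from Slc5a1 itself, since without it the list gave an adjusted p of 0.751 with an estimated correlation. In Akita vehicle samples p53 targets fell with the knockout (0 of 13 over all genes, 6 adjusted over the list alone, mean log2 -0.42, adjusted p = 0.00279 with an estimated correlation). This change was -0.34 (SE 0.10) with the sum of TPM as a covariate and -0.37 (SE 0.11) with the percent of mitochondrial rRNA (adjusted p = 0.00786 and 0.00892 with an estimated correlation). The interaction of diabetes and knockout for p53 targets had a mean log2 of -0.48 (adjusted p = 0.131 with an estimated correlation). Without the 3 libraries with the most RNA of other cells, the averaged knockout changes of p53 targets and interferon response had adjusted p values of 0.0822 and 0.104 with an estimated correlation. With the sum of TPM as a covariate the averaged change of p53 targets was -0.13 (SE 0.05) and both lists had an adjusted p of 0.148 with an estimated correlation. With the percent of mitochondrial rRNA p53 targets were at -0.16 (SE 0.06, adjusted p = 0.0822 with an estimated correlation). The interferon call was lost on leaving out any of 27 single libraries, up to 0.0858 without nondiabetic knockout dapagliflozin replicate 3.

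With dapagliflozin 1 gene passed in nondiabetic wild-type mice, Gm6999, a predicted gene named after its value was seen (log2 1.13, adjusted p 0.00397). It did not pass with array weights (0 genes) or in a fit of the compared groups alone (1 gene, 0 shared). Genes with the smallest p there, none past the threshold, were Asb8 (6.74 ± 2.76 to 14.6 ± 2.88 TPM), Gatad2a, a subunit of the NuRD chromatin complex (162 ± 15.6 to 227 ± 21.5 TPM), and the endothelial genes Vwf (5.1 ± 2.83 to 1.15 ± 0.799 TPM) and Mmrn2 (29.1 ± 10.5 to 15.8 ± 0.914 TPM; SD, n = 6 each). Mmrn2 reached an adjusted p of 0.0429 without nondiabetic vehicle replicate 6, where the count was 4. In Akita wild-type mice dapagliflozin called 0 genes in limma, and 1, Snord1c, without Akita vehicle replicate 2. At an unadjusted p under 0.05 there were 368 genes, or 2.39%, fewer than expected with no effect. Ppp1r14d stood at 2.3 ± 1.25 TPM with the drug and 0.32 ± 0.584 TPM without (SD, n = 5 and 6), and Bcas3 at 57.1 ± 17.2 and 39.3 ± 7.8 TPM. The small nucleolar RNAs Snord1c and Snord16a had blank cells, taken as 0, in all 5 dapagliflozin libraries and averaged 41.5 and 44.6 TPM with vehicle, where replicate 2 was blank as well.

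In knockout mice dapagliflozin called 0 genes in limma, both in nondiabetic and in Akita samples, with 731 and 483 at an unadjusted p under 0.05. Averaged over diabetes and genotype it also called 0, with 631. Muc1, the epithelial mucin, at 2.72 ± 1.75 TPM without and 6.34 ± 5.1 TPM with the drug (SD, n = 24 and 23), Hmces at log2 0.47, Trim30a at log2 -0.45 and Dpysl3 at log2 -0.39 had the smallest p values, each at an adjusted p of 0.999. In nondiabetic wild-type samples p53 targets had a mean log2 of 0.39 (0 of 13 over all genes, 2 adjusted over the list alone, adjusted p = 0.0644 with an estimated correlation). There endothelial and thick ascending limb markers were at mean log2 -0.27 and -0.65 (adjusted p = 0.366 for both with an estimated correlation). In Akita wild-type samples p53 targets had a mean log2 of -0.26 (adjusted p = 0.667 with an estimated correlation).

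The response of p53 targets to dapagliflozin differed between diabetic and nondiabetic wild-type mice, a call that was lost with the sum of TPM as a covariate (mean log2 -0.39, SE 0.15, adjusted p = 0.163 with an estimated correlation). That sum was 1420000 ± 323000 with vehicle and 1850000 ± 200000 with dapagliflozin in nondiabetic samples (SD, n = 6 each), and 1860000 ± 251000 and 1600000 ± 305000 in Akita samples (SD, n = 6 and 5). Without the covariate the interaction had a mean log2 difference of -0.65 over the 13 genes (0 past the threshold over all genes, 2 adjusted over the list alone, adjusted p = 0.00605 with an estimated correlation), and it kept that side of the threshold whichever library was left out. With the percent of mitochondrial rRNA as a covariate the difference was -0.57 (SE 0.16, adjusted p = 0.011 with an estimated correlation). Gene by gene, the interaction of diabetes and dapagliflozin called 0 genes in limma, with 681 at an unadjusted p under 0.05, and 2 without nondiabetic wild-type vehicle replicate 1. Knockout and dapagliflozin interacted on 0 genes in nondiabetic and 0 in Akita mice in limma, with 890 and 380 at an unadjusted p under 0.05. The nondiabetic count was 2 without nondiabetic wild-type vehicle replicate 5 or dapagliflozin replicate 3, and 1 without wild-type vehicle replicate 1, wild-type dapagliflozin replicate 5 or knockout dapagliflozin replicate 2 or 4.

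P53 targets were lower as a group with semaglutide than with vehicle in Akita wild-type mice, with a mean log2 of -0.58. The sum of TPM was also lower, at 1510000 ± 450000 against 1860000 ± 251000 with vehicle (SD, n = 5 and 6), and with it as a covariate the change was -0.45 (SE 0.11, adjusted p = 0.00104 with an estimated correlation). Of the 13 members, 0 passed over all genes and 7 fell adjusted over the list alone (adjusted p = 0.000872 with an estimated correlation). The p53 rise with diabetes and its falls in Akita mice with semaglutide, with knockout and with knockout plus dapagliflozin use the same 6 Akita vehicle libraries. The p53 interaction of diabetes and dapagliflozin uses them too. These p53 results are not independent of each other. Library numbers of semaglutide and Akita vehicle libraries do not overlap, and the number was not tried as a covariate for this change. Tnfrsf10b, a death receptor gene, went from 3.03 ± 1.1 to 0.963 ± 0.441 TPM (SD, n = 6 and 5), Phlda3 from 8.94 ± 2.52 to 3.35 ± 3.34 TPM and Mdm2 from 87.5 ± 12.2 to 61.3 ± 11.1 TPM. The p53 score was 3.11 ± 0.37 with semaglutide and 3.69 ± 0.15 with vehicle (SD, n = 5 and 6; 2-sided exact permutation p = 0.00649, and 0.186 after adjustment over 49 lists).

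No single gene passed for semaglutide in limma (0 genes, 800 at an unadjusted p under 0.05), and the smallest adjusted p was 0.109. Ugt1a10 stood at 2.42 ± 3.65 TPM with semaglutide and 16.9 ± 15.7 TPM with vehicle, Gbp4 at 10.8 ± 2.58 and 3.67 ± 0.731 TPM, and Pcgf3, a Polycomb subunit, at 47.2 ± 11 and 29 ± 10.6 TPM (SD, n = 5 and 6). Snord1c had blank cells, taken as 0, in all 5 semaglutide libraries. Gpd2 and Slc5a10, which rose with diabetes, had log2 changes of -1.17 and -1.17 with semaglutide (adjusted p 0.109 and 0.273). Both changes use the Akita vehicle libraries, so chance highs there favour opposite signs. With dapagliflozin in nondiabetic wild-type mice these genes were at log2 1.03 and 0.70 (limma adjusted p 0.238 and 0.609). All genes of the naming rule that passed for diabetes in vehicle samples also kept their sign there. Examples are Ctnna2 (log2 0.89), Ccng1 (0.69) and Vwf (-1.47), while Ephx1 was near 0 (0.02). Low or high values in nondiabetic vehicle libraries may thus carry part of these diabetes changes. In the fit without wild-type vehicle libraries, given under other observations, 12 genes passed, and Gpd2 and Slc5a10 were not among them. That fit does not settle the question. Preset camera called 17 lists, and the other 16 were lost with an estimated correlation, with glucose transporters, ChREBP and MondoA targets and cell cycle genes, all lower, at an adjusted p of 0.107. Array weights gave 12 genes, all lower. The count was 3 without semaglutide replicate 2 and 1 without Akita vehicle replicate 2, and 2 without the 3 libraries with the most RNA of other cells. All semaglutide libraries carry library numbers from 88 to 99 and all Akita vehicle libraries numbers from 1 to 82, so the ranges do not overlap. With the library number as a covariate 2 genes passed.

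Set directly against each other in Akita wild-type mice, semaglutide and dapagliflozin differed in 0 genes in limma, with 543 at an unadjusted p under 0.05, and in 1 without semaglutide replicate 2. P53 targets were at a mean log2 of -0.32 in semaglutide against dapagliflozin samples (adjusted p = 0.307 with an estimated correlation). The doses act on different targets and were not matched.

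Knockout together with dapagliflozin, which blocks both glucose carriers, was set against wild-type vehicle samples. In Akita mice 5 genes changed (6 against 6 libraries). Slc5a1 fell and Abhd1 rose, as in the knockout alone. Gm43694, a predicted gene named after its value was seen, fell (log2 -1.75, adjusted p 0.00128). Phlda3 fell from 8.94 ± 2.52 to 1.79 ± 1.21 TPM (SD, n = 6 each; adjusted p 0.039, and 0.188 without knockout dapagliflozin replicate 2). Snord1c had blank cells, taken as 0, in all 6 treated libraries (adjusted p 0.0375, and 0.157 without Akita vehicle replicate 4). With single libraries left out in turn, Phlda3 lost its call in 9 of 12 fits and Snord1c in 11. The count was 3 without Akita wild-type vehicle replicate 3, 4 or 6 or knockout dapagliflozin replicate 2, 3, 5 or 6.

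P53 targets fell as a group in this comparison (1 of 13 over all genes, 9 adjusted over the list alone, mean log2 -0.63, adjusted p = 0.000129 with an estimated correlation), with Ccng1 going from 91 ± 15.1 to 45.8 ± 6.25 TPM and Sesn2, a stress-induced sestrin, from 13.8 ± 4.3 to 7.24 ± 2.55 TPM. The sum of TPM was 1370000 ± 179000 in these samples and 1860000 ± 251000 in wild-type vehicle samples (SD, n = 6 each), and with it as a covariate the p53 change was -0.44 (SE 0.11, adjusted p = 0.00138 with an estimated correlation). The p53 fall uses the same 6 Akita vehicle libraries as the p53 rise with diabetes and is not independent of it. Glucose transporters as a group gave an adjusted p of 0.874 with an estimated correlation once Slc5a1 was left out. Transcripts of the mitochondrially encoded respiratory chain were at mean log2 -0.95 (adjusted p = 0.315 with an estimated correlation). In nondiabetic mice 3 genes changed, Slc5a1, Abhd1 and Gm43694 (log2 -2.21, adjusted p 5.06e-06), the last named after its value was seen, and 5 passed without knockout dapagliflozin replicate 1. P53 targets were at mean log2 0.24 there (adjusted p = 0.973 with an estimated correlation).

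Across genes, the changes with each treatment in Akita mice were compared with the diabetes change. Because both contain the Akita vehicle libraries, these were split 3 and 3 between the changes, averaged over 20 splits, and 1000 simulated groups without effect gave the chance values. Over 15424 genes, which are not independent replicates, the correlation was -0.26 for semaglutide (simulated values from -0.18 to 0.17), -0.19 for knockout with dapagliflozin (-0.16 to 0.17), -0.14 for the knockout (-0.18 to 0.15) and -0.11 for dapagliflozin (-0.15 to 0.18). The one-sided simulated shares, taken on the covariance without sharing and adjusted over the 4 treatments, were 0.012 for semaglutide, 0.028 for the combination and 0.0799 for each of the others. The simulation drew on the spread within groups. A technical shift common to all Akita vehicle libraries is therefore not in the chance values, and splitting these libraries does not remove it. Such a shift was not tested here. With all vehicle libraries shared, the covariance was -0.104 for semaglutide against a simulated -0.058, and -0.085, -0.074 and -0.069 for the combination, the knockout and dapagliflozin against -0.058, -0.058 and -0.057. When Akita vehicle replicate 5 was left out, the correlations without sharing were -0.17 for semaglutide, -0.10 for the combination, -0.07 for the knockout and -0.03 for dapagliflozin. Without replicate 2 dapagliflozin was at -0.18. Of the 52 genes that rose with diabetes, Ugt1a10 fell with the knockout and Phlda3 with the combination. These calls share the Akita vehicle libraries, so chance highs there favour such overlaps, and the overlap was not tested.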

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

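The test of called genes for their share near Slc5a1 and the tests of p53 targets with the sum of TPM and with mitochondrial rRNA were chosen after the result was seen. For the other tests in this part the expected outcomes were written down before they were run. The covariates for the lists and leaving out the 3 libraries were nevertheless chosen after the main results were seen.

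Genes that changed in the Sglt1 knockout lie near Slc5a1. Outside Slc5a1 itself, 5 of the 6 called genes, among them Abhd1, Tyms, Cgref1 and Sema3c, lie within 20 Mb of it, where 1.58% of tested genes lie (Fisher's exact p = 5.52e-09, 2-sided). Among uncalled genes, 11.8% near Slc5a1 and 7.1% elsewhere had an unadjusted p under 0.05 (odds ratio 1.75, 1.13 to 2.61, Fisher's exact p = 0.0105, 2-sided). DNA of the strain in which the knockout was made, carried along around Slc5a1, is a candidate explanation. An effect of the altered locus on its neighbours and weaker responses elsewhere in the genome were not tested and stay open.

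P53 targets were higher in Akita than in nondiabetic vehicle samples by a mean log2 of 0.78. With the score of other cell types as a covariate the change was 0.77 (SE 0.12), with the S1 and S2 score 0.78 and with the library number 0.79. It was 0.61 (SE 0.10) with the sum of TPM of each library and 0.70 (SE 0.11) with the percent of mitochondrial rRNA, so part of the change goes with these library measures. The values argue against each of the 5 trends alone as the whole cause. A response of tubule cells to diabetes was not tested, nor were other differences between the groups, and these stay open.

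Endothelial, macrophage and interferon lists were lower in Akita samples, by a mean log2 of -0.26 (SE 0.06) averaged over genotype and drug (adjusted p 0.0868, 0.045 and 0.0808 with an estimated correlation). Without the 3 libraries with the most RNA of other cells it was -0.19 (SE 0.05), with adjusted p values of 0.24, 0.125 and 0.184, so the macrophage call ended as its change went from -0.31 to -0.22, and these libraries carry part of the change. The changes of the 10 lists of other cell types, from -0.31 for macrophages to 0.14 for erythroid cells, did not spread beyond chance (permutation p = 0.431, one-sided on their variance). The chance SD of these changes was 0.07 for endothelium and 0.25 for erythroid cells, so the test could miss real differences between lists. The interferon list was not among the 10. Less RNA of all other cells in the Akita dissections is therefore neither shown nor excluded. A change in those cells themselves stays open as well.

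Single libraries stood apart from their group in 15 of 214 groups of values, 7.01%, where a rule of this kind marks some by chance. In nondiabetic wild-type vehicle samples these were Ctnna2 in replicate 2 (1.45 TPM, nearest other 4.15), Ugt1a10 in replicate 4 (2.42, the others blank and taken as 0), Bcas3 in replicate 1 (71.4, nearest 59.6), Gatad2a in replicate 2 (132, nearest 163) and the polyol and fructose score in replicate 2 (6.6, nearest 7.32). In Akita wild-type vehicle samples they were Vwf in replicate 1 (0.216 TPM, nearest 0.913), Snord1c and Snord16a in replicate 2 (blank, taken as 0, for both, nearest 22.1 and 33) and Pcgf3 in replicate 6 (49.8, nearest 28.1). Elsewhere they were Abhd1 in Akita knockout vehicle replicate 5 (75.5 TPM, nearest 45.1), Gbp4 in semaglutide replicate 6 (15.4, nearest 10.2), Slc5a2 in nondiabetic wild-type dapagliflozin replicate 1 (95.4, nearest 18.9) and Slc5a1 in Akita wild-type dapagliflozin replicate 4 (42.8, nearest 70.7). The failed-repair score was 3.79 in Akita wild-type dapagliflozin replicate 3 (nearest 4.03), and Akita knockout dapagliflozin replicate 4 had 16947 genes with a value (nearest 17863).

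The response of p53 targets to dapagliflozin differed between Akita and nondiabetic wild-type mice by a mean log2 of -0.65. This difference contains both wild-type vehicle groups, so it is not independent of the p53 rise with diabetes. With the sum of TPM as a covariate the difference was -0.39 (SE 0.15) and the call ended as it shrank (adjusted p 0.00605 before, 0.163 after, with an estimated correlation). With the percent of mitochondrial rRNA as a covariate the difference was -0.57 (SE 0.16) and the call was kept (adjusted p 0.011 with an estimated correlation). Causes beyond these library measures are not weighed here and stay open.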

How the results depend on the processing

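The S1 and S2 score, the fits without 3 libraries (those with the most RNA of other cells), the lists without Slc5a1, covariates for the lists, and leaving out single libraries for the lists and the correlations were chosen after results were seen, and the other alternatives before. No paired analysis was possible because the labels give each library a number of its own and no replicate numbers, which were assigned here.

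Gene counts moved most for diabetes. In vehicle samples the 60 genes became 34 with the compared groups alone (27 shared), 143 with the library number (59 shared), and 39 to 148 with single libraries left out (39 without Akita vehicle replicate 4, 148 without nondiabetic vehicle replicate 5). Averaged, the 149 genes became 83 with the score of other cell types (71 shared), 304 with the library number (149 shared), 74 without the 3 libraries (67 shared), and 97 to 204 with single libraries left out (204 without nondiabetic wild-type vehicle replicate 5). The cause of these moves was not tested.

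For the knockout, array weights gave 8 genes in Akita mice (from 4) and 19 averaged (from 8), and the nondiabetic count was 5 without the 3 libraries (from 3). With single libraries left out the counts were 3 to 7 in Akita mice and 8 to 10 averaged, and 3 in each nondiabetic fit. Knockout with dapagliflozin in Akita mice gave 3 genes with a pseudocount of 0.1, 9 with array weights and 3 to 6 with single libraries left out (from 5), and in nondiabetic mice 3 to 5 (from 3).

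For dapagliflozin in nondiabetic wild-type mice array weights gave 0 genes, the compared groups alone 1 (0 shared) and single libraries left out 1 to 4 (from 1). In Akita wild-type mice the count was 1 without the 3 libraries and 0 to 1 with single libraries left out (from 0). Semaglutide gave 12 genes with array weights, 2 with the library number, 2 without the 3 libraries and 0 to 3 with single libraries left out (from 0), and 0 to 1 against dapagliflozin. The interaction of diabetes and dapagliflozin gave 1 without the 3 libraries and 0 to 2 with single libraries left out. That of knockout and dapagliflozin in nondiabetic mice gave 2 with the S1 and S2 score, 1 without the 3 libraries and 0 to 2 with single libraries left out.

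Over all comparisons, 175 list results passed preset camera. With an estimated correlation 17 did, 17 with the score of other cell types added, 12 without the 3 libraries, 13 without Slc5a1, 13 with the sum of TPM and 12 with the percent of mitochondrial rRNA. With the sum of TPM, lists that turned direction, none past the threshold, were, at these adjusted p values with an estimated correlation: ribosomal proteins for diabetes in vehicle samples (0.692), dapagliflozin in nondiabetic wild-type mice (0.705), semaglutide (0.961), the averaged knockout (0.815), the interaction of diabetes and dapagliflozin (0.72) and that of knockout and dapagliflozin in nondiabetic mice (0.978); nuclear-encoded oxidative phosphorylation for diabetes in vehicle samples (0.75), semaglutide (0.961) and the averaged knockout (0.815); the mitochondrially encoded list for diabetes in vehicle samples (0.956), the averaged knockout (0.815) and the interaction of diabetes and dapagliflozin (0.91); the citric acid cycle for the averaged knockout (0.975); and endothelium for the interaction of diabetes and dapagliflozin (0.997). For knockout with dapagliflozin in Akita mice ribosomal proteins, nuclear-encoded oxidative phosphorylation, citric acid cycle, NRF2 targets and polyol and fructose metabolism turned (1 for each). With mitochondrial rRNA, ribosomal proteins turned for dapagliflozin in nondiabetic wild-type mice (0.986) and the mitochondrially encoded list for the averaged knockout (0.895). The intercalated cell list turned direction for averaged diabetes with the score of other cell types (adjusted p 0.739, and 0.864 with an estimated correlation). Without the 3 libraries further lists turned (adjusted p preset, then estimated): ribosomal proteins (0.628, 0.99) and nuclear-encoded oxidative phosphorylation (0.924, 0.99) for diabetes in vehicle samples, ribosomal proteins for dapagliflozin in nondiabetic wild-type mice (0.119, 0.873) and for the interaction of diabetes and dapagliflozin (0.974, 0.991), stroma for knockout with dapagliflozin in nondiabetic mice (0.657, 0.991), and endothelium (0.724, 0.962) and glutathione detoxification (0.826, 0.962) for the interaction of knockout and dapagliflozin in nondiabetic mice.

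With all Akita vehicle libraries in both changes, the correlations with the diabetes change were -0.49 for dapagliflozin, -0.63 for semaglutide, -0.53 for the knockout and -0.58 for the combination, where simulation without effect gave -0.47, -0.47, -0.49 and -0.50. With single libraries left out and no sharing, the correlation was -0.31 to -0.17 for semaglutide, -0.24 to -0.10 for the combination, -0.19 to -0.07 for the knockout and -0.18 to -0.03 for dapagliflozin (the first without Akita vehicle replicate 2, the second bound without replicate 5). Of 110 results of named genes, none turned direction in any alternative run, but calls were lost: 19 without the 3 libraries, 16 with the compared groups alone, 11 with the score of other cell types, 8 with array weights, 4 with a pseudocount of 0.1, and 2 each without a filter and with rescaling. Across the fits with single libraries left out, 162 of 3234 results lost their call. Most of these genes were picked for small p in the same data, so a kept direction was likely in advance.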

Other observations

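The comparisons of genes and of the p53 score over the other 3 pairs of groups were chosen after results were seen, and the splits were planned before.

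Diabetes can be examined without any wild-type vehicle library. Between the other 3 pairs of Akita and nondiabetic groups, 12 genes passed in limma, 11 higher and 1 lower in Akita samples. Afm (log2 0.66), Ctnna2 (0.76), Pklr (1.01), Folh1 (0.74) and Sult1c2, a sulfotransferase (0.57), were among the higher ones, and Laptm5 (-0.88) was the lower one. With semaglutide, 10 of the 12 had the opposite sign, and Laptm5 (-0.11) and Trmt9b (0.57) did not. None of these semaglutide changes passed in limma. They are measured against the Akita wild-type vehicle libraries, and the share of opposite signs over all genes was not counted, so reversal cannot be read from this. Trmt9b was also at -0.65 for diabetes in wild-type vehicle samples, against 0.81 in the other pairs.

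The p53 score differed between Akita and nondiabetic groups by 0.78 in wild-type vehicle samples (2-sided exact permutation p = 0.00216) and by 0.30 in knockout vehicle samples (p = 0.026). With dapagliflozin the differences were 0.13 in wild-type (exact permutation p = 0.203) and -0.09 in knockout samples (exact permutation p = 0.279).

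Gene counts were set against those of 100 splits of the same libraries with the real one included. Chance can be excluded for the count of averaged diabetes. It called 149 genes and no other split more than 1, so that 1 split, the real one, reached the count. For the averaged knockout it was 8 genes against at most 2, reached by 1 split. For the knockout in Akita mice it was 4 against at most 3, and for knockout with dapagliflozin in Akita mice 5 against at most 4, each reached by 1 split, a margin of 1 gene. Each of these knockout counts holds Slc5a1, Abhd1 and Gm43694, which passed in each comparison of knockout with wild type. In Akita mice the splits cannot exclude chance for the rest, Ugt1a10, Phlda3 and Snord1c. Their calls ended in 5, 9 and 11 of 12 fits with single libraries left out. Splits were counted at the settings chosen first alone, and at other settings the 2 Akita counts went from 3 to 8 and from 3 to 9. Diabetes in vehicle samples called 60 genes, 3 splits reached that, and the highest other split called 408, which points to a structure among these libraries.

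Chance cannot be excluded for the number of genes in the knockout in nondiabetic mice (3 genes, reached by 6 splits, highest other 59), dapagliflozin in nondiabetic wild-type mice (1 gene, 28 splits, highest other 1277) and knockout with dapagliflozin in nondiabetic mice (3 genes, 23 splits, highest other 1007). The high counts of other splits point to a structure among the nondiabetic libraries. For both knockout counts this concerns the number alone, since the 3 genes are Slc5a1, Abhd1 and Gm43694 (highest adjusted p 3.91e-08 and 5.06e-06), and these also passed in the Akita libraries, which argues against chance for the genes themselves.

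A count of 0 is reached by any split, here by all 100, so the splits test nothing where limma called 0 genes. The highest other split was 1 for dapagliflozin averaged, in Akita wild-type and in Akita knockout mice (631, 368 and 483 genes at an unadjusted p under 0.05). It was also 1 for semaglutide and for semaglutide against dapagliflozin (800 and 543), and 2 for dapagliflozin in nondiabetic knockout mice (731). For the interactions the highest other split was 2 for diabetes with dapagliflozin and for diabetes with knockout (681 and 618), 37 for knockout with dapagliflozin in nondiabetic mice (890) and 0 in Akita mice (380).

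For lists past preset camera, 1 split, the real one, reached the count of averaged diabetes (26 lists, highest other 24). Another split came close to it, so the count alone is weak evidence against chance. With an estimated correlation 7 lists passed in this comparison. Chance cannot be excluded for the number of lists in diabetes in vehicle samples (20 lists, 19 splits, highest other 28), the averaged knockout (11 lists, 27 splits, highest other 26) and semaglutide (17 lists, 9 splits, highest other 25).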
